A study of Mus musculus with 16 samples.

How the data were processed

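RNA was measured in 16 libraries of sorted 4T07 cells: GFP and mCherry cells of 3 mixed tumours injected with Jedi T cells on day 7, the same of 3 tumours injected on day 15, and mCherry cells of 4 control tumours. Per the labels' protocols, tumours were digested for 20 minutes at 37 °C, stained for CD45 and with DAPI and sorted. The gate on CD45 is not given in the sources used here. The raw counts per gene were made by a sequencing company for the authors, per the labels' protocols, on mm10, per the submitters' processing notes. The aligner, counter and annotation are not given in the sources used here. The authors also deposited DESeq2 tables of GFP against mCherry cells for each day, per the submitters' processing notes. Per the file headers these hold log2 fold changes with standard errors, the Wald score, the p-value with its adjusted p-value, and baseMean, the mean of normalized counts over the libraries. The version, design and filter behind them are not given in the sources used here.

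Everything reported was computed from the counts. Each count table holds 49315 genes. In each, 176 have no symbol, and these hold at most 0.0110% of a library's counts; 195 share a symbol with another and were kept apart by identifier. An empty line at the end of the day 15 table was dropped. Of 49139 Ensembl identifiers, 48968 have a record in GENCODE M21 (GRCm38), which gave the coordinates of all 141 named genes. Libraries held 9412040 to 32808354 counts, and 1.12% to 2.00% of counts lay in mitochondrially encoded genes. Between replicates of a group, gene counts varied with a chi-square per degree of freedom of 5.34 to 92.1, beyond counting error, so that errors come from the spread between tumours.

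The day 7 columns are numbered 2 to 4 and the labels 1 to 3, so these were matched as groups, as were the 4 control columns. Tumour and control numbers in the text are the numbers of the count columns within each day or group, not the tumour numbers of the labels. Pairing by shared number was checked before any fits were compared. Residual correlations of the GFP and mCherry libraries of one number were 0.110 to 0.162 on day 7, against −0.130 to 0.00919 for other pairs. On day 15 they were 0.0896 to 0.232, against −0.183 to 0.0186. The smallest lies below the bound of 0.1 set for columns paired by number alone, but the day 15 pairs are given by the labels. Residuals were centred on the mean of each colour, which pushes other pairs down where those of one number lie above 0. With 3 libraries per colour few pairings are possible, so chance could give the same match. The day 7 pairing thus rests mainly on the shared column numbers.

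Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), normalized with TMM and tested with edgeR 4.0.16 quasi-likelihood F-tests in R 4.3.3, adjusted by Benjamini and Hochberg, with the threshold at an adjusted p of 0.05. GFP and mCherry cells were compared within each day with tumour as a block, which left 2 residual degrees of freedom. Day 15 mCherry and day 15 GFP cells were each compared with the controls without a block (3 against 4 libraries). The difference between days was the contrast of the GFP effects in the 12 mixed tumour libraries with tumour as a block. The day 15 libraries and controls serve in more than one of these comparisons, so that their results are not independent. CPM are given with SD over libraries, SE is the log2 fold change over the square root of its F statistic, tumour medians use log2 CPM with a prior count of 2, and n counts tumours.

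In all, 32 gene lists (17 of pathways, 12 of cell types, 3 of RNA quality) were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, where at least 5 members were measured. This test sets the members of a list against the other genes. Its p therefore rests on the spread across genes more than on that between tumours. Called members are counted with adjustment over all genes and, where given, adjusted over the list alone. The sign of the list median differed from that of the test in 2, 2, 2, 1 and 4 lists of the comparisons in the order above, none of them called. Genes were named by a rule. It took the 6 largest rises and 6 largest falls (4 and 4 for the controls against GFP cells and the difference between days) among called genes with a mean log2 CPM of at least 1 and the same sign in every tumour, or no overlap of groups. It added the 2 members of smallest p of each core or called list, the 2 most abundant markers of each called cell type or quality list, and Mki67, Cdkn1b, Hif1a, B2m, Cd274 and Ptprc. Not every gene that the rule named is printed.

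Comparisons, lists, tests, alternatives and the naming rule were chosen before the data were examined. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter of 50 counts, no block, leaving out each tumour or library, a joint fit of the 10 libraries of run 2, a correlation estimated per list, and fry. Thinning all libraries to the shallowest was chosen after the data were seen. The tests were checked on simulated counts with the depth of the libraries and the fitted spread of each gene. These held no differences between tumours and no correlation between genes. Changes were given only to genes with a mean count above 50. The shares recovered may therefore be higher than for real genes, above all for those with fewer counts. Changes of 2-fold were recovered in 89.6% of cases on either day, 83.6% against the controls and 64.2% for the difference between days. For 1.5-fold changes these shares were 44.8% on day 7, 62.7% on day 15, 53.7% for mCherry and 34.3% for GFP cells against controls, and 16.4% for the difference. False calls were 8 of 164 on day 7, 16 of 184 on day 15, 6 of 160 for mCherry and 6 of 147 for GFP cells against controls, and 9 of 129 for the difference.

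The deposited DESeq2 tables were used only as a check. Their log2 fold changes lay within 0.01 of a DESeq2 fit with tumour as a block for 98.8% (day 7) and 99.6% (day 15) of genes, against 52.3% and 64.0% without the block. One entry of the day 15 table has a baseMean of 22515900, which is the size of a library total, and was left out. The age of the control tumours is not given in the sources used here.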

Results

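RNA was sequenced from sorted cells of mouse tumours grown from 4T07, a mammary carcinoma line, in the mammary fat pad of female Balb/cJ x C57BL/6J hybrids. Mixed tumours began from 250000 cells, GFP-transduced and mCherry-transduced in equal parts. The mice then received Jedi T cells, which recognise a peptide of GFP and here lacked PD1, on day 7 or day 15 of tumour growth, and the tumours were taken 7 days later. GFP cells that outlasted the T cells and untargeted mCherry cells were sorted from each of 3 tumours per injection day, which gave 3 libraries per colour and day. A further 4 libraries came from control tumours of mCherry cells alone that received no Jedi T cells. The 16 libraries held 9412040 to 14535791 counts in the day 7 GFP group and 12942893 to 19970822 in the day 7 mCherry group. The range was 21183324 to 24880582 in day 15 GFP, 21832170 to 22248031 in day 15 mCherry and 24367417 to 32808354 in the controls. Tumours are numbered here as in the count columns, 2 to 4 on day 7 and 1 to 3 on day 15. The day 7 libraries were sequenced in run 1 and all others in run 2, so that day and run coincide. No library came from GFP cells in a tumour without Jedi T cells, so each GFP to mCherry difference holds the reporter and the T cell attack together.

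In tumours injected on day 7, the comparison of GFP with mCherry cells asks how cells that survived T cell attack differed from untargeted cells of the same tumour. The libraries of surviving GFP cells held more RNA of interferon-induced and antigen presentation genes, and less RNA of cell division, sterol synthesis and chemokine genes. Macrophage and endothelial markers were lower in these libraries too (medians −2.53 and −3.44). Whether host cells in the mCherry libraries account for the falls in chemokine genes was not tested. Cd274, which encodes the PD1 ligand PD-L1, stood at 126 ± 23.5 CPM (SD, n = 3) in GFP cells and 24.0 ± 5.44 CPM in mCherry cells, 5.28 times higher (adjusted p = 2.76e-06). Of 30 interferon response genes, 25 rose and 1 fell, with a median log2 fold change of 1.64, and 26 rose and 2 fell when adjusted over the list alone. The fall was in Cxcl9, a chemokine that draws T cells, at −2.91 (named after its value was seen). Stat2, a transcription factor of interferon signalling, was 4.33 times higher and Gbp3, a guanylate-binding protein of cell-autonomous defence, 4.09 times higher. All 17 MHC class I presentation genes rose, with a median of 0.84, and all 17 did so when adjusted over the list alone. Among them were Nlrc5, the transactivator of MHC class I genes (144 ± 13.4 against 44.8 ± 3.08 CPM, n = 3), and H2-T23, a non-classical MHC class I gene (3.21 times higher). B2m, the MHC class I light chain, was 1.48 times higher, a call that ended without tumour 2 (adjusted p = 0.0544) and without the tumour block (adjusted p = 0.0824). The list tests gave adjusted p = 1.46e-53 for the interferon genes and 1.85e-24 for MHC class I. With an estimated correlation, neither list passed (adjusted p = 0.306 and 0.377).

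Genes of proliferation were lower in the day 7 GFP cells. Of 28 G2/M and mitosis genes, 25 fell (27 adjusted over the list alone; median −0.80; adjusted p = 2.58e-15, and 0.464 with an estimated correlation). Of 28 S phase and DNA replication genes, 21 fell (24 over the list alone; median −0.62; adjusted p = 1.12e-11, and 0.477 with an estimated correlation). With fry neither list passed (adjusted p = 0.178 and 0.163). Plk1, a mitotic kinase, was 2.29 times lower and Cdc45, a replication fork helicase factor, 1.89 times lower. Mki67, the antigen of the Ki-67 proliferation stain, fell from 183 ± 46.7 to 108 ± 64.7 CPM (n = 3; log2 fold change −0.89, SE 0.15, adjusted p = 0.00397), and its call ended without the tumour block (adjusted p = 0.159). The tumours differed in this respect, with median mitosis differences of −1.23 and −1.06 in tumours 2 and 3 and −0.25 in tumour 4. Cdkn1b, which encodes the cell cycle inhibitor p27, stood at 17.6 ± 2.16 against 20.4 ± 4.74 CPM (n = 3; adjusted p = 0.433). Of 13 cell cycle inhibitor and dormancy genes, 3 rose and 4 fell, among the latter Txnip, a thioredoxin-binding protein, and Foxo1, a transcription factor of quiescence, and the list did not pass (adjusted p = 0.503).

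Further day 7 groups moved with these. Of 17 sterol and fatty acid synthesis genes, 11 fell (median −0.87; adjusted p = 3.96e-14, and 0.169 with an estimated correlation). Of 21 chemokines and cytokines, 15 fell and 2 rose (median −1.08; adjusted p = 6.18e-12, and 0.377 with an estimated correlation). Csf3, the granulocyte growth factor, was 5.82 times lower, at 8.09 ± 4.23 against 46.9 ± 19.8 CPM (n = 3), and Il33, an alarmin, 5.64 times lower. In the list of 19 immune inhibitory ligands, which also holds enzymes, 6 genes rose and 4 fell (median 0.21; adjusted p = 0.0230, and 0.464 with an estimated correlation). Hmox1, the haem oxygenase, was 4.35 times higher, at 223 ± 113 against 49.2 ± 21.2 CPM (n = 3). This list lost its call without the tumour block (adjusted p = 0.198) and without tumour 2 (adjusted p = 0.109). Of 18 unfolded protein and integrated stress genes, 7 rose (median 0.27; adjusted p = 2.32e-04, and 0.464 with an estimated correlation), and of 25 oxidative phosphorylation genes, 8 fell (median −0.27; adjusted p = 0.00168, 0.137 with fry and 0.656 with an estimated correlation). The lists of hypoxia (adjusted p = 0.473), glycolysis (0.347), NF-kB targets (0.344), mesenchymal transition (0.180), epithelial identity (0.0503), stemness and Wnt (0.123) and p53 targets (0.522) did not pass. The epithelial list passed with DESeq2 size factors (adjusted p = 0.0497), with fry (0.0489), after thinning (0.0138) and without tumour 3 (0.00196), the mesenchymal list with fry (0.0459), and the stemness list without tumour 4 (0.00987). Tumour medians ran from −0.69 to −0.67 for epithelial, −0.25 to −0.01 for mesenchymal and 0.01 to 0.48 for stemness genes. Members of these lists were called, among them the hypoxia marker Car9, 1.61 times higher, the oxygen sensor Egln3, 1.94 times lower, and the collagen crosslinker Lox, 3.05 times lower. Eno2, an enolase, was 1.70 times higher, a call that ended without tumour 3 (adjusted p = 0.102). Hif1a, the hypoxia-inducible factor, stood at 172 ± 11.3 against 179 ± 19.2 CPM (n = 3; adjusted p = 0.758).

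Markers of other cell types were also lower in the day 7 GFP libraries. Of 19 macrophage and monocyte genes, 17 fell (median −2.53; adjusted p = 4.00e-48, and 0.0923 with an estimated correlation), and all 10 endothelial genes tested fell (median −3.44; adjusted p = 5.31e-15, and 0.384 with an estimated correlation). Lyz2, a lysozyme of myeloid cells, was 6.57 times lower, at 61.6 CPM against 374 CPM (n = 3), and Ptprc, which encodes the CD45 antigen used in the stain, at 1.41 ± 0.585 against 7.85 ± 2.79 CPM. Eng, an endothelial receptor, fell by 0.88, a call that ended without tumour 3 (adjusted p = 0.0900) or tumour 4 (0.0886). The list of dendritic cell and MHC class II genes did not pass (adjusted p = 0.298), but passed without tumour 2 (0.00677) or tumour 3 (0.0307). That of fibroblasts (median −0.73) did not pass (0.783, with the test upward against the sign of the median), and without tumour 2 it was called lower (7.21e-07). The RNA quality lists of mitochondrially encoded (0.178), ribosomal protein (0.344) and immediate early genes (0.473) did not pass either, though the mitochondrial list passed with fry (0.0459). Too few members were measured to test T and NK cell (2 genes), neutrophil (3), B and plasma cell (1), pericyte (2), adipocyte (1), mammary epithelium (3), skeletal muscle (2) and erythroid (1) markers. Of these, S100a8 of neutrophils (−1.37) and Fabp4 of adipocytes (0.147 ± 0.127 against 1.93 ± 1.47 CPM, n = 3) fell and Csn3, a casein, rose (1.61), all named after their values were seen.

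Over all 14578 genes tested on day 7, 1296 rose and 1360 fell, 317 and 554 of them by over 2-fold. Large rises were in H19, an imprinted non-coding RNA (log2 fold change 3.96, SE 0.44), Ngfr, the low-affinity neurotrophin receptor (3.84, SE 0.28), the complement gene C2 (3.68, SE 0.35), the heat shock protein Hspb7 (3.00, SE 0.43) and the osteocalcin gene Bglap2 (2.94, SE 0.18). Angptl7, a secreted angiopoietin-like protein, reached 1433 ± 602 CPM against 181 ± 50.5 (n = 3). Among the deepest falls were Ibsp, a sialoprotein of bone matrix (−4.36, SE 0.17), and 5 genes with few counts in GFP cells, for which levels are given. Gpihbp1, a capillary lipase anchor, stood at 0.0891 ± 0.154 against 4.89 ± 3.76 CPM (n = 3), Igfbp3, a growth factor carrier, at 0.250 ± 0.135 against 8.14 ± 4.57, and Plvap, of endothelial fenestrae, at 0.356 ± 0.125 against 9.11 ± 3.74. Cd33, a myeloid lectin, stood at 0.359 ± 0.158 against 9.45 ± 2.28 CPM and Esam, an endothelial adhesion molecule, at 0.244 ± 0.146 against 5.56 ± 3.18. On the genome build GRCm38, Cd274 lies on chromosome 19 from 29367455 to 29388095, Ngfr on chromosome 11 from 95568818 to 95587735, Angptl7 on chromosome 4 from 148495183 to 148500460 and H19 on chromosome 7 from 142575529 to 142578143. The difference between colours had the same sign in all 3 tumours for 52.3% of genes. The count of 2656 calls fell to 1753 without tumour 2 and 1156 without tumour 3, and was 4558 without tumour 4.

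**Figure D1:**
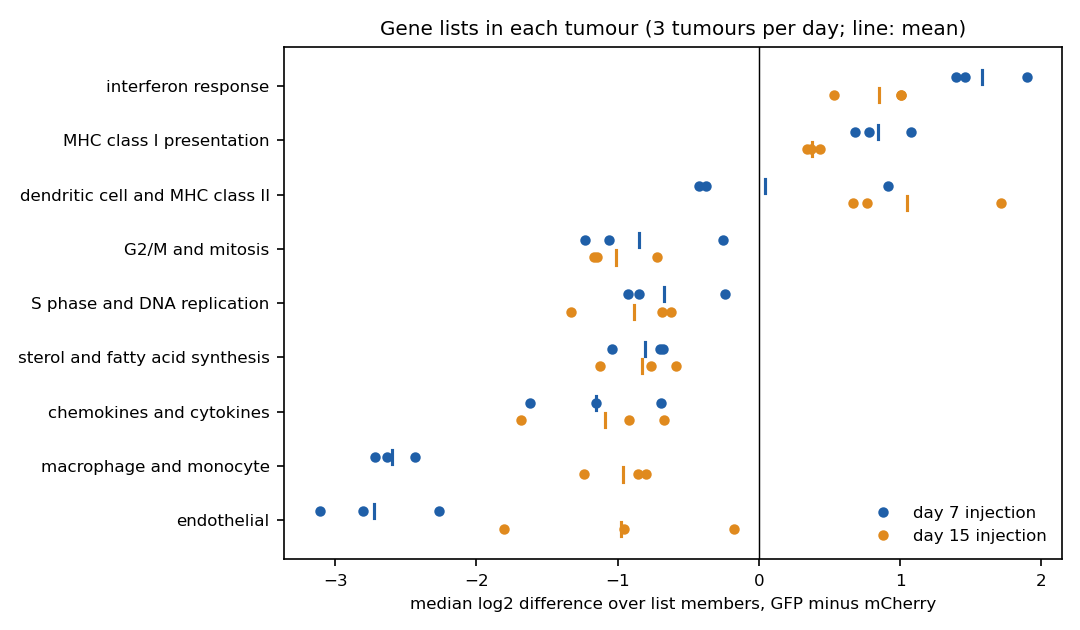
Median log2 difference between GFP and mCherry cells over the members of 9 gene lists, a point per tumour, with a line at the mean of the 3 tumours of each injection day. The interferon medians lie between 1.40 and 1.90 on day 7 and between 0.53 and 1.01 on day 15, and the mitosis medians lie below 0 in every tumour.

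In tumours injected on day 15, the same comparison was made 8 days later in tumour growth. The libraries of surviving GFP cells again held more interferon, MHC class I and Cd274 RNA and less RNA of cell division, sterol synthesis and chemokines than the mCherry libraries. Whether host cells account for the falls in chemokines was not tested on this day either. Cd274 was 3.06 times higher, at 177 ± 69.2 against 58.7 ± 23.3 CPM (n = 3; adjusted p = 4.10e-05). Of 30 interferon genes, 22 rose and 2 fell (25 and 2 adjusted over the list alone; median 0.80; adjusted p = 3.45e-28, and 0.438 with an estimated correlation). The falls were in Cxcl9 (−1.36) and Cxcl10 (−0.67), both chemokines that draw T cells and both named after their values were seen. Igtp, an interferon-induced GTPase, was 2.55 times higher, at 593 ± 285 against 228 ± 91.1 CPM (n = 3), and Irgm2, of the same family, 2.17 times higher. Irgm2 missed the threshold without the tumour block (adjusted p = 0.0504). Of 17 MHC class I genes, 12 rose (15 over the list alone; median 0.36; adjusted p = 6.92e-10, and 0.438 with an estimated correlation), with H2-T23 2.03 times and Nlrc5 1.77 times higher. B2m was 1.37 times higher, and without tumour 3 its adjusted p was 0.0713.

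All 28 mitosis genes fell on day 15 (28 over the list alone; median −1.03; adjusted p = 8.17e-44, and 0.438 with an estimated correlation). Of 28 replication genes, 26 fell (27 over the list alone; median −0.89; adjusted p = 1.36e-21, and 0.443 with an estimated correlation). Mki67 fell from 384 ± 84.1 to 164 ± 34.4 CPM (n = 3; log2 fold change −1.22, SE 0.13, adjusted p = 2.28e-04). Kif20a, a kinesin of cytokinesis, was 2.45 times lower, Bub1, a spindle checkpoint kinase, 2.21 times lower, and Mcm4, a subunit of the replicative helicase, 2.02 times lower. Of 15 cell cycle inhibitor and dormancy genes, 4 rose and 3 fell, and the list did not pass (adjusted p = 0.275). Its risen members included Nr2f1, a nuclear receptor linked to dormancy, at 393 ± 16.8 against 265 ± 11.2 CPM (n = 3), while Cdkn1b stood at 226 ± 31.6 against 195 ± 13.4 CPM (adjusted p = 0.176).

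Of 17 sterol and fatty acid genes, 15 fell on day 15 (median −0.80; adjusted p = 5.84e-21, and 0.438 with an estimated correlation). Of 19 chemokines and cytokines, 11 fell and 1 rose (median −1.19; adjusted p = 1.02e-08, and 0.443 with an estimated correlation), with Csf3 4.42 times and Cxcl2, a neutrophil chemokine, 4.68 times lower. Of 18 NF-kB targets, 8 fell (median −0.30; adjusted p = 2.41e-04, and 0.565 with an estimated correlation). Of 18 mesenchymal transition genes, 7 fell and 1 rose (median −0.39; adjusted p = 5.40e-05, and 0.438 with an estimated correlation), with the integrin chain Itgb3 3.04 times and Lox 3.35 times lower. Of 17 glycolysis genes, 6 rose (median 0.31; adjusted p = 0.00223, and 0.603 with an estimated correlation), among them the enolase Eno2 and the hexokinase Hk1. Eno2 missed the threshold without the tumour block (adjusted p = 0.0504). Of 25 oxidative phosphorylation genes, 5 fell (median −0.17; adjusted p = 0.0230, and 0.565 with an estimated correlation), a call lost without tumour 2 (adjusted p = 0.0683). Of 18 unfolded protein and stress genes, 5 rose and 1 fell (median 0.14; adjusted p = 0.0475, and 0.624 with an estimated correlation), a call lost without tumour 1 (adjusted p = 0.119) or tumour 3 (adjusted p = 0.128). The hypoxia list lay at adjusted p = 0.0501, passed without the block (0.0180), with DESeq2 size factors (0.0451) and after thinning (0.0487), and passed without tumour 2 (0.0130) or tumour 3 (3.96e-04). Its median differences were 0.50, 0.15 and −0.08 in tumours 1, 2 and 3, and without tumour 1 the list did not pass. In it Car9 was 1.95 times higher and the stress gene Ddit4 1.60 times lower, while Hif1a stood at 217 against 246 CPM (n = 3; log2 fold change −0.18, SE 0.08, adjusted p = 0.152). The lists of immune inhibitory ligands (adjusted p = 0.228), epithelial identity (0.248), stemness and Wnt (0.215) and p53 targets (0.715) did not pass. In the inhibitory ligand list the enzyme Hmox1 was 4.02 times higher, and the list passed without tumour 1 (adjusted p = 0.0286). With fry none of the 16 lists called on day 15 passed, the smallest adjusted p being 0.0671 for mesenchymal genes, with 0.0897 for mitosis and interferon, 0.112 for replication and 0.0771 for MHC class I.

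The cell type markers took different directions on day 15. Of 8 dendritic cell and MHC class II genes tested, 7 rose (median 1.02; adjusted p = 6.29e-07, and 0.443 with an estimated correlation). All 7 belong to MHC class II presentation, among them Cd74, the invariant chain (622 ± 365 against 260 ± 88.1 CPM, n = 3), and H2-Ab1, a class II chain (2.02 times higher). Without the tumour block both missed the threshold (adjusted p = 0.0750 and 0.113). Of 13 macrophage genes, 8 fell (median −0.95; adjusted p = 8.66e-05, and 0.438 with an estimated correlation), and of 12 endothelial genes, 5 fell (median −1.05; adjusted p = 8.04e-04, and 0.593 with an estimated correlation). Cd14, a myeloid endotoxin receptor, was 1.75 times lower, Cd68, a macrophage lysosomal protein, stood at 9.62 ± 3.62 against 5.97 ± 1.99 CPM (n = 3; adjusted p = 0.0617, called higher without tumour 3 at 0.0178 and without a filter at 0.00117), and Ptprc at 0.595 ± 0.0461 against 1.17 ± 0.257 CPM (adjusted p = 0.105). Of the RNA quality lists, 2 were called higher, and whether handling or RNA quality differed between the sorted fractions was not tested. Of 20 immediate early and dissociation stress genes, 10 rose and 1 fell (median 0.34; adjusted p = 4.04e-04, and 0.603 with an estimated correlation). Among them Fosb, an AP-1 subunit, was 1.29 times higher and lost its call without the block (adjusted p = 0.203) and without tumour 3 (0.319). In the other RNA quality list called, 3 of 26 ribosomal protein genes rose (median 0.20; adjusted p = 0.00370, and 0.692 with an estimated correlation), a call lost without tumour 1 (adjusted p = 0.281). The fibroblast list, with 2 genes higher, 5 lower and a median of −0.52, did not pass (adjusted p = 0.531, with the test upward against the sign of the median), and without tumour 2 it was called lower (1.44e-09). The pericyte (adjusted p = 0.228), adipocyte (0.248), skeletal muscle (0.704) and mitochondrial (0.916) lists did not pass. The adipocyte list (adjusted p = 0.00888) and the skeletal muscle list (8.66e-05) passed without tumour 1.

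Over 14260 genes tested on day 15, 1275 rose and 1507 fell, 216 and 376 of them by over 2-fold, and the count fell from 2782 to 1736 without tumour 3. H19 rose by 2.84 (SE 0.42), with a wide spread between tumours (16.2 ± 18.1 against 1.65 ± 0.529 CPM, n = 3). Other large rises were in Aldh1a1, a retinaldehyde dehydrogenase (2.75), Angptl7 (2.52), Ngfr (2.51), Ogn, a matrix proteoglycan (2.32), and Mapt, the microtubule protein tau (2.26). Among genes above the expression bound of the naming rule with the same sign in every tumour, the deepest falls were in Acsbg1, an acyl-CoA synthetase (−4.37), Moxd1, a monooxygenase (−4.34), and Ibsp (−4.16). Tnip3, an inhibitor of NF-kB signalling (−3.10), Cilp, a cartilage matrix protein (−2.88), and Itga2, a collagen receptor chain (−2.80), followed.

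**Figure D2:**
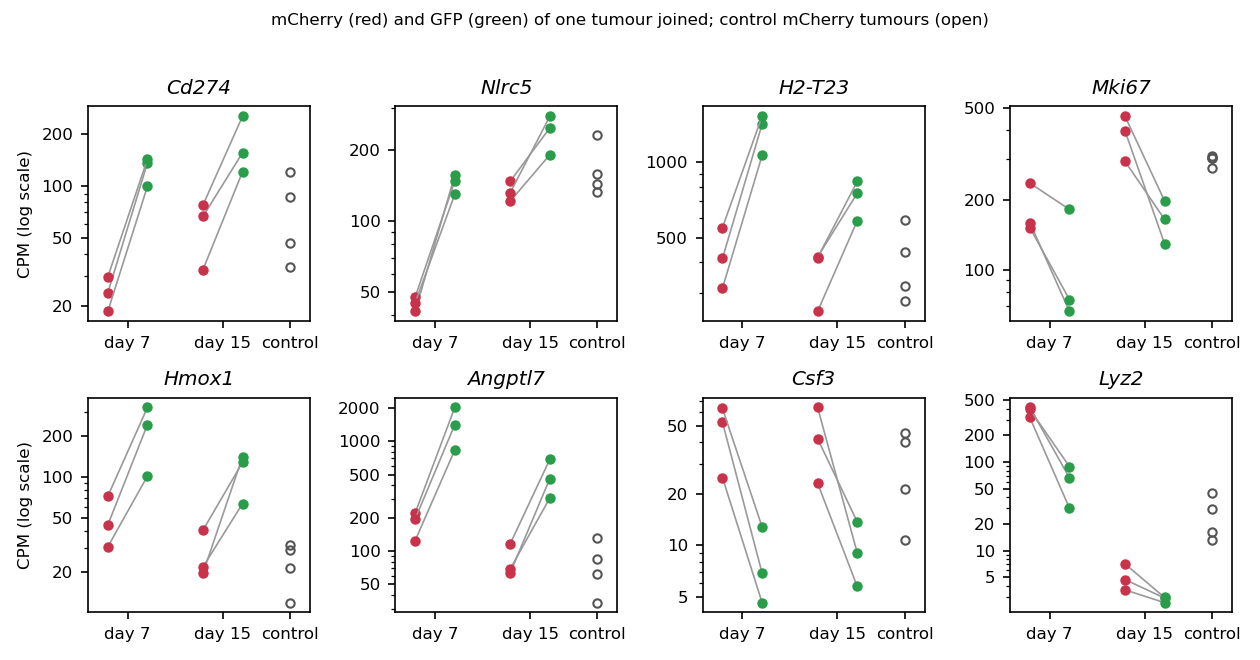
CPM on a log axis of 8 named genes in each mCherry (red) and GFP (green) library, with a line joining the libraries of a tumour, and in the 4 control tumours (open circles). Cd274 is higher and Csf3 lower in the GFP library of each of the 6 tumours, and Lyz2 in mCherry cells stands at 374 CPM on day 7.

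The changes on both days overlapped. Of 12988 genes tested on both days, 681 rose on both where 121 were expected by chance (Fisher's exact test, odds ratio 23.3, 95% interval 20.2 to 26.8), and 718 fell on both where 135 were expected (odds ratio 22.2, interval 19.3 to 25.6). Only 4 genes were called in opposite directions. Genes are not independent replicates, so the expected counts and intervals do not measure the spread between tumours. Across the same genes, the log2 fold changes of the 2 days had r = 0.712. Without the tumour block the shared calls numbered 915 in place of 1399.

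**Figure D3:**
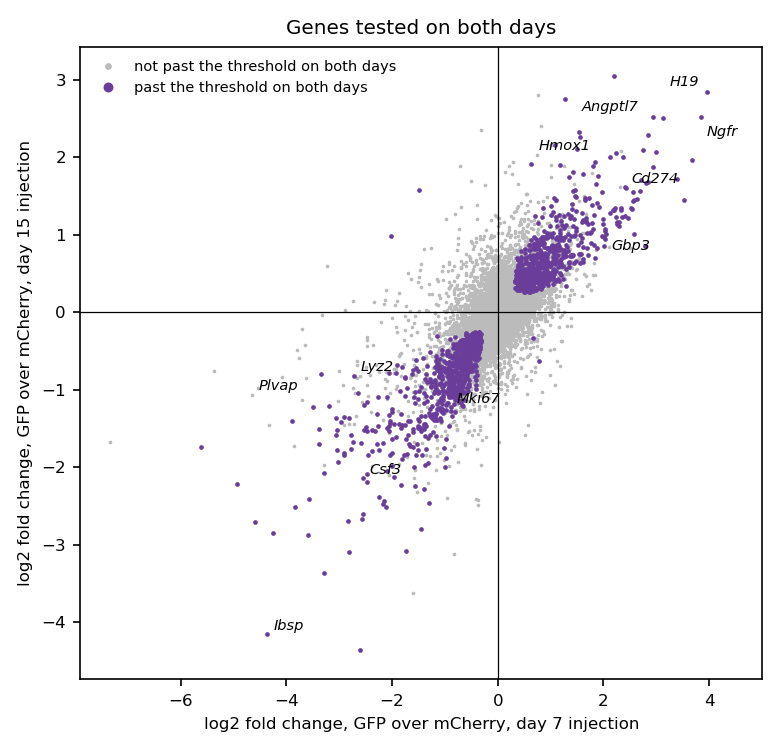
Log2 fold change of GFP over mCherry cells in day 7 tumours (x axis) and day 15 tumours (y axis), a point per gene tested on both days, with genes past the threshold on both days in purple. The 681 genes that rose and 718 that fell on both days lie along the diagonal, and Gbp3 is among the interferon genes below the diagonal.

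The difference between the days in the GFP to mCherry contrast was tested directly in the 12 libraries of the mixed tumours. The rise of interferon and MHC class I genes was smaller in day 15 tumours. Of 30 interferon genes, 4 had a smaller fold on day 15 (19 adjusted over the list alone), and the list median was lower by a log2 difference of −0.79 (adjusted p = 2.13e-26, and 0.275 with an estimated correlation). The median of MHC class I genes differed by −0.47, with 3 of 17 genes called, 13 over the list alone (adjusted p = 2.19e-17, and 0.275 with an estimated correlation). Igtp differed by −1.17 (SE 0.20), Gbp7, a guanylate-binding protein, by −1.13, Tap1, a peptide transporter subunit, by −0.93, and Tapbp, the peptide-loading chaperone tapasin, by −0.89. The depletion of macrophage genes (median difference 1.52; adjusted p = 1.03e-21, and 0.0514 with an estimated correlation) and of endothelial genes (1.89; adjusted p = 4.64e-12, and 0.279 with an estimated correlation) was smaller on day 15. Lyz2 differed by 1.88, Plvap by 3.59 and Arg1, an arginase of myeloid cells, by 2.48, and the plasma kininogen Kng2 (3.83) and the membrane protein Gpm6b (2.55) showed the other large positive differences. Each of the 12 genes called and named by the rule for this difference lost its call in at least 1 alternative. The mitosis and replication medians differed by −0.16 (adjusted p = 0.0356, and 0.801 with an estimated correlation) and −0.18 (adjusted p = 0.0295, and 0.8 with an estimated correlation). Both turned to the opposite direction without day 7 tumour 4 (adjusted p = 0.0203 and 0.320), and the replication list also without day 15 tumour 1 (adjusted p = 0.878). The mitosis list lost its call without day 15 tumour 1 (adjusted p = 0.436) or 3 (0.243). Hypoxia genes (median difference 0.23; adjusted p = 5.26e-06, and 0.482 with an estimated correlation) and ribosomal protein genes (0.26; adjusted p = 1.03e-08, and 0.497 with an estimated correlation) kept their calls whichever tumour was left out. In all, 18 of 27 lists were called for this difference, and 6 of the 18 kept their call in every alternative other than fry and the estimated correlation. With fry only the macrophage list passed (adjusted p = 0.0262), against 0.151 for interferon, 0.109 for MHC class I, 0.156 for endothelial, 0.748 for mitosis and 0.729 for replication genes and 0.373 for hypoxia and ribosomal genes.

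Of 16588 genes, 17 had a higher and 18 a lower contrast on day 15, a count of 35 that became 2 without the tumour block and 140 with DESeq2. It was 4 without day 7 tumour 2, 127 without day 7 tumour 4, 3 without day 15 tumour 1 or tumour 2 and 9 without day 15 tumour 3. Day and run coincide, and some levels differed far more between runs than between colours: Cdkn1b stood at 226 CPM in day 15 and 17.6 CPM in day 7 GFP cells.

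The mCherry cells of day 15 tumours were compared with mCherry cells of control tumours to ask whether untargeted cells in attacked tumours differed. The groups differ both in T cell transfer and in the presence of GFP cells in the tumour, and the age of the control tumours is not given. A difference here can therefore not be assigned to the T cell attack. No gene passed the threshold with edgeR out of 14800 tested (2104 genes had an unadjusted p under 0.05), and DESeq2 called 130 genes higher and 94 lower. Of 27 lists 5 were called, none of them with an estimated correlation or with fry (adjusted p = 0.0875 for replication, 0.559 for mitosis, 0.334 for sterol and adipocyte and 0.476 for macrophage genes). Replication genes had a median of 0.32 (23 of 28 higher over the list alone; adjusted p = 3.50e-23, and 0.542 with an estimated correlation) and mitosis genes 0.37 (0 over the list alone; adjusted p = 6.06e-13, and 0.654 with an estimated correlation). Sterol and fatty acid genes had a median of 0.42 (10 of 17 over the list alone; adjusted p = 1.22e-12, and 0.542 with an estimated correlation). Prim1, a primase subunit, stood at 31.3 ± 3.07 CPM (n = 3) against 20.4 ± 1.90 in controls (n = 4), and Idi1, an isomerase of sterol synthesis, at 15.8 ± 4.86 against 7.83 ± 1.74 CPM, each with an adjusted p of 0.251. Macrophage genes were lower as a list (median −1.35; 11 lower and 1 higher of 17 over the list alone; adjusted p = 7.97e-12, and 0.566 with an estimated correlation). Adipocyte genes were higher as a list (1.30; 6 of 7 over the list alone; adjusted p = 2.29e-07, and 0.542 with an estimated correlation). Lyz2 stood at 5.23 ± 1.82 against 26.1 ± 14.5 CPM and the adipocyte lipid carrier Fabp4 at 24.5 ± 5.31 against 10.5 ± 7.42 CPM. The interferon (adjusted p = 0.0909) and MHC class I lists (0.293) did not pass. The interferon list passed without day 15 tumour 1 (adjusted p = 3.80e-05), control 1 (0.0128) or control 4 (1.72e-08), and the MHC class I list without day 15 tumour 3 (0.0295) or control 2 (3.09e-04). Leaving out control 1 brought in hypoxia (0.00114), MHC class II (0.00870), endothelial (0.0128) and epithelial genes (0.00104), control 3 stress genes (8.98e-05), and control 4 ribosomal (0.0146) and immediate early genes (0.0156). Leaving out day 15 tumour 1 brought in epithelial and endothelial genes (0.0399 each), tumour 2 stress and immediate early genes (0.00410 each), and tumour 3 chemokines (0.00630). Without control 4, 7 genes were called. The count of 5 lists became 8 without day 15 tumour 1, day 15 tumour 3 or control 4 and 10 without control 1.

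Day 15 GFP cells were compared with the same control tumours, a contrast in which reporter, T cells and tumour differ together. As against the mCherry cells beside them, the GFP cells held less RNA of mitosis genes and more of interferon genes. Of 28 mitosis genes, 24 fell (27 over the list alone; median −0.65; adjusted p = 9.28e-21, and 0.505 with an estimated correlation), among them Cenpa, the centromeric histone, at 47.6 ± 6.09 CPM (n = 3) against 83.6 ± 8.78 (n = 4). Of 28 replication genes, 12 fell (18 over the list alone; median −0.51; adjusted p = 1.03e-08, and 0.505 with an estimated correlation). Of 30 interferon genes, 8 rose (13 over the list alone; median 0.89; adjusted p = 1.03e-08, and 0.505 with an estimated correlation), with Usp18, an interferon-induced protease, 2.96 times and the tethering protein Bst2 2.55 times higher. Usp18 lost its call without GFP tumour 1 (adjusted p = 0.0701) or 2 (0.0526), and Bst2 without GFP tumour 1 (0.0720), 2 (0.0801) or 3 (0.0763) or control 3 (0.0690). MHC class I genes had a median of 0.29, with 2 of 17 called, 3 over the list alone (adjusted p = 0.00234, and 0.593 with an estimated correlation), and the list lost its call without GFP tumour 3 (adjusted p = 0.0670). Chemokines (median −1.27; adjusted p = 3.00e-04), sterol genes (−0.37; 5.46e-04), mesenchymal genes (−0.43; 0.00160), oxidative phosphorylation genes (−0.23; 0.00160), macrophage genes (−2.77; 2.86e-14) and endothelial genes (−1.77; 0.00148) were lower as lists. With an estimated correlation these had adjusted p = 0.505, except for the endothelial list at 0.512. Ccl2, a monocyte chemokine, was 3.48 times and C1qa, a complement chain of macrophages, 13.0 times lower. Ccl2 lost its call without GFP tumour 1 (adjusted p = 0.0639) or 3 (0.0541). Glycolysis (median 0.32; adjusted p = 0.00251, and 0.512 with an estimated correlation) and hypoxia genes (0.28; adjusted p = 0.00486, and 0.593 with an estimated correlation) were higher, and Car9 was 2.18 times higher. The hypoxia list lost its call without control 4 (adjusted p = 0.0604).

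In this contrast the NF-kB (median −0.28; adjusted p = 0.0175) and epithelial lists (−0.54; 0.0402) were lower, both at 0.505 with an estimated correlation. The keratin gene Krt18 was 2.84 times lower, a call lost without GFP tumour 1 (adjusted p = 0.0699) or 2 (0.0687). The epithelial list lost its call without GFP tumour 2 (adjusted p = 0.110) or 3 (0.180) and without control 3 (0.0549) or 4 (0.256), while the NF-kB list lost it without control 1 (0.0772). The adipocyte (median 1.09; adjusted p = 0.0167), ribosomal (0.12; 0.0175) and immediate early lists (0.20; 0.0183) were higher, with adjusted p of 0.512, 0.693 and 0.635 with an estimated correlation. The adipocyte list lost its call without GFP tumour 1 (adjusted p = 0.0819) or control 1 (0.0567), the ribosomal list without GFP tumour 1 (0.309), control 1 (0.0691) or control 4 (0.184), and the immediate early list without GFP tumour 2 (0.0514) or control 4 (0.256). The MHC class II list (median 1.18; adjusted p = 0.0529) passed without GFP tumour 1 (0.0173) or control 1 (0.00189). The fibroblast list (−0.79; 0.0626) passed without GFP tumour 2 (0.0425) or control 1 (0.00591), 2 (0.0115) or 3 (0.0279). With fry none of the 17 lists called here passed, with adjusted p from 0.0795 to 0.307. Over 14801 genes, 902 rose and 1031 fell, and leaving out a library moved the count of 1933 to 287 (GFP tumour 1), 520 (GFP tumour 2), 914 (GFP tumour 3), 928 (control 2) or 807 (control 3). Large rises were in H19 (3.65, SE 0.76) and Hspb7, a small heat shock protein (3.08, SE 0.29). Of the 38 genes called and named by the rule here, 8 kept their call in every alternative, among them Hspb7, Cenpa, Car9 and C1qa, and H19 lost it without GFP tumour 1 (adjusted p = 0.0577) or control 3 (0.0572). Deep falls were in the fibrillar collagen genes Col5a2 (−5.61, SE 1.06) and Col1a2 (−4.93, SE 1.00), whose levels varied widely between control tumours (186 ± 201 CPM for Col1a2, n = 4). Both lost their calls without GFP tumour 1 (adjusted p = 0.0714 for Col5a2 and 0.0633 for Col1a2), 2 (0.0647 and 0.0683) or 3 (0.0530 and 0.0619). Tumour 2 stood apart for these genes on day 15 as well, with Col1a2 at 0.997 CPM in its mCherry cells against 85.7 and 120 CPM in the other 2 tumours.

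**Figure D4:**
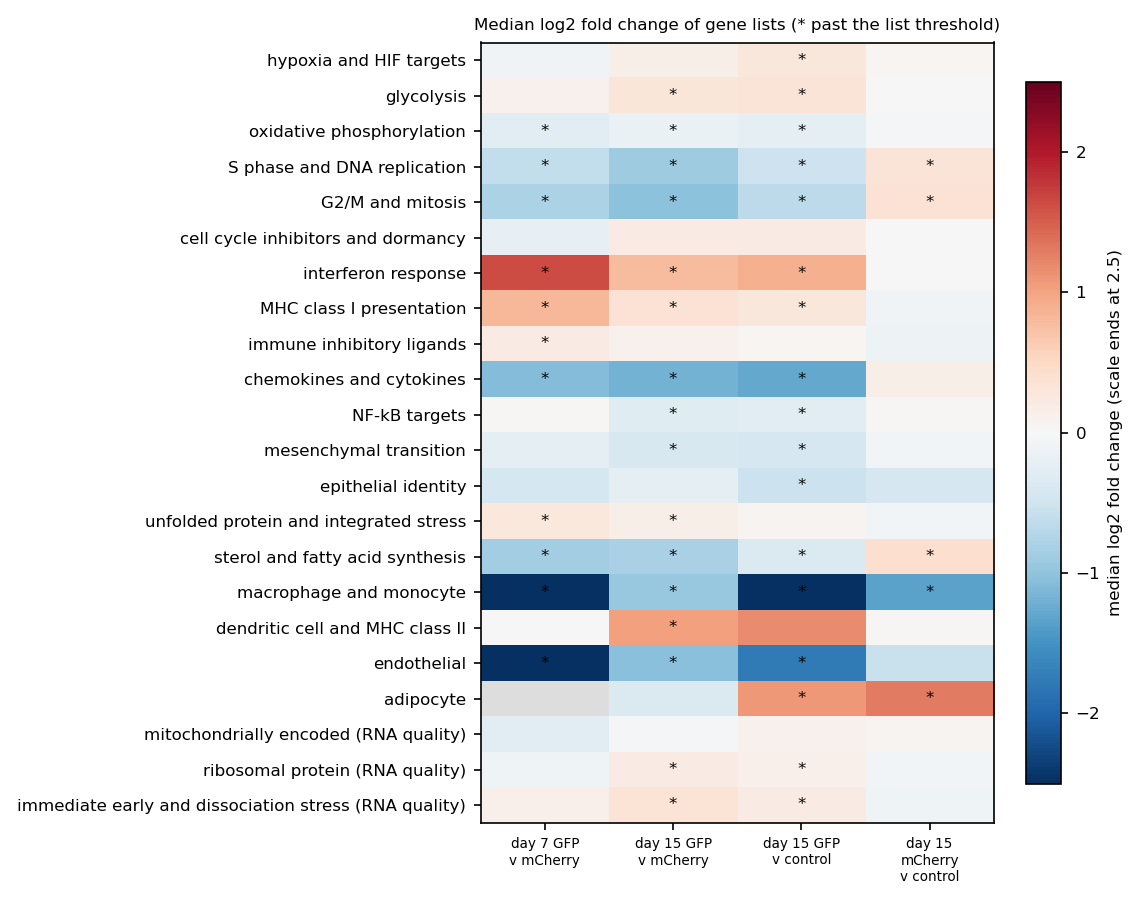
Median log2 fold change (colour) of 22 gene lists in the 4 contrasts between groups, with an asterisk where the list passed the threshold of the preset-correlation test and grey where fewer than 5 members were measured. Mitosis genes are lower in both GFP contrasts of day 15 (−1.03 and −0.65), with a list median of 0.37 in mCherry cells against controls, where none of the genes was called and the list did not pass with fry (adjusted p = 0.559) or an estimated correlation (0.654).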

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

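Of the tests in this part, those of host cells through Xist, of immune cells in the GFP fraction, of cycling host cells (both tests, the bound on their marker RNA included) and of a fixed difference between the populations were chosen only after the result was seen. Thinning was also added after the data were seen, with its prediction written before it was run, and the splits were planned.

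Differences between the days were singled out where the direct test passed. Among genes these were Arg1 (2.48), Batf2 (−1.57), Gbp3 (−0.98), Gbp6 (−1.13), Gbp7 (−1.13), Gpm6b (2.55), Igtp (−1.17), Irgm2 (−1.17), Kng2 (3.83), Lyz2 (1.88), Nlrc5 (−0.86), Plvap (3.59), Tap1 (−0.93) and Tapbp (−0.89), each as day 15 minus day 7 in log2 fold change. Each of the 12 of these that the naming rule gave lost its call in at least 1 alternative. Among lists the median differences were −0.79 for interferon, −0.47 for MHC class I, 1.52 for macrophages, 1.89 for endothelium, 0.70 for MHC class II and 0.66 for adipocytes. They were 0.23 for hypoxia, 0.19 for glycolysis, 0.0675 for oxidative phosphorylation, −0.18 for replication, −0.16 for mitosis and 0.18 for cell cycle inhibitors. NF-kB targets differed by −0.26, epithelial genes by 0.27, stress genes by −0.12, mitochondrial genes by 0.18, ribosomal genes by 0.26 and immediate early genes by 0.19. With an estimated correlation none of these 18 lists passed, the smallest adjusted p being 0.0514 for macrophages. Day and run coincide in all of these.

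Leaving out a tumour ended many of these list calls. Adjusted p values without day 7 tumours were, for tumour 2, 0.242 for oxidative phosphorylation, 0.156 for epithelial genes and 0.0795 for mitochondrial genes. For tumour 3 they were 0.0828 for glycolysis, 0.211 for oxidative phosphorylation, 0.0624 for stress genes, 0.0695 for MHC class II, 0.0848 for adipocytes and 0.0516 for mitochondrial genes. For tumour 4 they were 0.207 for glycolysis, 0.459 for cell cycle inhibitors, 0.159 for NF-kB targets, 0.0591 for epithelial genes, 0.315 for stress genes and 0.224 for adipocytes. Without day 15 tumour 1 they were 0.680 for glycolysis, 0.0682 for epithelial genes and 0.117 for adipocytes. Without tumour 2 they were 0.0815 for oxidative phosphorylation and NF-kB targets, 0.365 for stress genes and 0.0695 for mitochondrial genes. Without tumour 3 they were 0.182 for oxidative phosphorylation, 0.137 for MHC class II, 0.0575 for mitochondrial genes and 0.0917 for immediate early genes. Calls were also gained, for fibroblasts without day 7 tumour 2 (0.00746) and for skeletal muscle without day 15 tumour 1 (7.55e-06).

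Only the 4 controls were searched for a library that stands apart. For 91 genes and lists in them, 7 held such a library by the gap over the range, where chance gives about 1 in 20, or 4.55. They were Atp5c1 (0.837) and P4ha1 (0.9002) in control 1, Tnfrsf10b (0.839) in control 2, Hk1 (0.923) and the stress list (0.910) in control 3, and Cfd (0.891) and Cyp51 (0.839) in control 4. The cause was not tested. On day 7, tumour 4 lay apart from tumours 2 and 3 in chi-square per degree of freedom, without such a search. In mCherry cells it was 92.1 and 88.1 against them and 10.5 between them, and in GFP cells 26.8 and 26.1 against 5.34. The top 10 genes held 13.5% of counts in its mCherry library, against 9.33% and 9.86%. Its mitosis difference was the smallest of day 7 (−0.25).

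Interferon and MHC class I genes were higher in GFP cells. With the lower depth of the day 7 GFP libraries evened out by thinning, 25 of 30 interferon genes were still called higher and 1 lower. These calls thus did not need the unequal depth. The median of 1.67 after thinning cannot decide more, since thinning keeps expected fold changes and the fits scale for library size. Immune cells left in the GFP fraction are argued against by a macrophage median of −0.946 on day 15 and lower still on day 7, although few T cell genes could be measured, MHC class II genes were higher on day 15, and the macrophage gene Cd68 was called higher on day 15 without tumour 3. A fixed difference between the 2 transduced populations could not be decided. The interferon list changed by −0.735 between days with no overlap of tumours, but the exact permutation p of 0.1 was the smallest possible. Day and run coincide, and the macrophage median also differed between days (−1.59, day 7 minus day 15). Each macrophage median covers the genes tested on that day, more of them on day 7. Some or all of the interferon rise may thus be fixed. Exposure to T cells stays open as a biological explanation, as no GFP cells without T cells were sequenced.

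Mitosis and replication genes were lower in GFP cells. After thinning, 25 of 28 mitosis genes were still called lower on day 7, so these calls did not need the unequal depth. The mitosis median of −0.81 after thinning cannot decide more, since thinning keeps expected fold changes. For immune and endothelial cells on day 15, the mCherry excess of marker RNA was at most 0.0746 of the excess of mitosis RNA in any tumour. This argues against cycling cells of these types only if they hold about as much marker RNA as mitosis RNA, which was not measured. Cycling host cells stay open on day 7, where that ratio was 0.356 to 1.36 and the mitosis median differed by 0.233 from day 15, under the spread between tumours of 0.521. Fibroblasts stay open on both days. Their summed marker RNA had no mCherry excess in 5 of 6 tumours (−339, −250 and 19.8 CPM on day 7, −146, −651 and −116 CPM on day 15), but a few abundant genes can carry such sums. The median over the markers was lower in GFP cells in tumours 3 and 4 of day 7 (−0.89 and −1.47) and tumours 1 and 3 of day 15 (−1.04 and −1.05). It was higher in tumour 2 of each day (0.59 and 0.44). Tumour cells may also share these markers. A fixed difference in growth between the populations may also account for it, as the change between days was −0.164 (exact permutation p = 0.7), and this design cannot part it from slower division of the cells that survive T cells.

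Macrophage and endothelial markers were lower in GFP cells. Host cells in the mCherry fraction may account for this: Xist, which marks cells of the female host only if the tumour line lacks it, was lower in the GFP library of all 6 tumours, by a median log2 difference of −1.72. The counts of Xist were few, and its level in 4T07 cells was not measured apart. After thinning, 16 of 19 macrophage genes were still called lower on day 7, so these calls did not need the unequal depth. The macrophage median of −2.63 after thinning cannot decide more, since thinning keeps expected fold changes.

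Splits of the libraries into groups of the same sizes were too few on either day to give a share under 0.05: the real count of calls was 2656 on day 7 and 2782 on day 15, and the highest other was 0, so that 1 of 10 splits was as large on each day. Only 4 of the 10, the real one included, part all 3 pairs, and the others part 1 pair and so rest on a single tumour, where 0 calls say little. For the difference between days, 1 of 10 splits was as large (35 calls, highest other 3), again too few. For day 15 GFP cells against controls, 1 of 35 was as large, with 1933 calls and 168 at the highest other. For day 15 mCherry cells against controls, all 35 of 35 were as large, since no gene was called, and the highest other held 12.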

How the results depend on the processing

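Thinning was chosen only after the result was seen; the other alternatives were planned. With a correlation estimated per list, 0 lists passed in each of the 5 comparisons, and with fry 0 passed on day 15, in mCherry cells against controls and in GFP cells against controls, and 1 for the difference between days. On day 7 fry passed 11 lists, as many as the preset correlation but not the same: 3 were lost, mitosis (adjusted p = 0.178), replication (0.163) and oxidative phosphorylation (0.137), and 3 gained, mesenchymal and mitochondrial (0.0459 each) and epithelial genes (0.0489). DESeq2 called 224 genes in mCherry cells against controls, where edgeR called none, and 140 for the difference between days. That difference held 354 calls without a filter, 15 with the stricter filter, 2 without the block and 68 with DESeq2 without the block. The overlap of the days was 915 without the block. Leaving out a tumour or library gave 1156 to 4558 genes on day 7, 1736 to 2546 on day 15, 0 to 7 in mCherry cells and 287 to 2093 in GFP cells against controls, and 3 to 127 for the difference. Lists then numbered 12 to 13 on day 7, 16 to 17 on day 15, 6 to 10 in mCherry cells and 13 to 18 in GFP cells against controls, and 11 to 16 for the difference. The fibroblast test, upward but not called with all tumours while its median was negative, was called downward without tumour 2 on day 7 (adjusted p = 7.21e-07; 0.949 without tumour 3) and on day 15 (1.44e-09; 0.401 without tumour 3). For the difference between days, the replication list ranged from 5.10e-05 without day 7 tumour 3 to 0.878 without day 15 tumour 1, where it took the opposite direction. The mitosis list ranged from 6.49e-07 without day 7 tumour 2 to 0.436 without day 15 tumour 1, and took the opposite direction without day 7 tumour 4 (0.0203).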

Other observations

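The test of imprinted genes in this part was chosen only after the result was seen. Other values here come from the gene tests above, and no further test was run.

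Several further list members were called, and were named after their values were seen. Cdh1, the epithelial cadherin, was higher in GFP cells on day 7 (log2 fold change 1.92) and day 15 (1.36), while Krt18 was lower on both days (−1.72 and −0.98). The median of their epithelial list was lower in GFP cells in all 3 tumours of each day. Among immune inhibitory genes Cd24a was higher on both days (1.18 and 1.05), Ptgs2, a prostaglandin synthase, as well (1.12 and 0.80), and Entpd1, an ectonucleotidase, was lower (−2.48 and −2.19). Tgfbi rose on day 15 (0.98) in a mesenchymal list that fell. Among fibroblast genes on day 15 Dcn, a proteoglycan, was higher (1.25) and Col1a1 lower (−2.52).

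H19 was among the largest rises on both days, and Igf2, its imprinted neighbour, was higher on day 7 (0.62) and day 15 (1.92). Other imprinted genes fell on day 15: Meg3 stood at 0.189 ± 0.256 against 1.81 ± 1.66 CPM and Grb10 at 0.170 ± 0.198 against 0.773 ± 0.512 CPM (n = 3). Of a list of imprinted genes written because of H19, 2 of 10 rose on day 7 (median 0.26), and 4 rose and 2 fell of 13 on day 15 (median 0.04). Its limma camera test had an upward direction on both days, with an unadjusted p = 0.0241 as the larger of the days. The p rose without H19 (0.193 on day 7 and 0.0757 on day 15) and with an estimated correlation (0.231 and 0.134), so a shift of imprinted loci as a group may or may not be present.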
